A study of Lactiplantibacillus plantarum WCFS1 with 6 samples.

How the data were processed

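Expression was measured with arrays of 2 dyes on total RNA of *Lactiplantibacillus plantarum* WCFS1. The 6 arrays join 6 RNA samples in a loop: 2 glucose cultures at OD600 1 and 2 scFOS cultures at OD600 1 and at OD600 1.5. Groups were taken from the hybridisation descriptions and the culture, carbohydrate and density given for each dye. Some titles give other culture numbers than these fields, and the fields were used. 1 array set scFOS cultures 3 and 4 against each other at each density, and 4 arrays set scFOS against glucose, 2 per density and in opposite dye orientation.

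The deposited values are log2 ratios per probe and array as read here. They are log ratios centred near 0, and their base is not given in the sources used here: a base of 10 would need ratios of up to 2710000, while the natural logarithm is not excluded. Scanner intensities were not used here, so that background, saturation and dependence on intensity were not analysed. Background correction and normalization by the authors are not given in the sources used here. All 6 columns were used. Their medians were -0.0018 and 0.0047 on the within-scFOS arrays at OD600 1 and 1.5, 0.0055 and -0.022 on the OD600 1 arrays, and -0.0051 and -0.021 on the OD600 1.5 arrays; whether and how the authors centred or scaled them stays unknown.

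The direction of the ratios was checked on the pairs of arrays with opposite dye orientation. Values of such a pair should oppose if each is a ratio of the dyes. Across features their correlation was -0.368 at OD600 1 and -0.351 at OD600 1.5. At OD600 1.5, channel order and dye order differ, and a ratio of channel 2 over channel 1 would give a positive correlation, so the reading by dye was kept. Which dye was divided by which stays open. A sucrose gene cluster that had been meant to settle it has no named probe here. Fits were run as Cy5 over Cy3, and the sides A and B carry that convention; the other reading turns all sides together and changes no size, test or count.

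Gene names came from the platform annotation: 1146 probes had 1 gene, 0 had several and 8461 had none and are unnamed here. A reference gene table of another strain's assembly (ASM991365v1) matched 0 of the gene IDs and was not used, and no coordinates are given. Probes with a value on all 6 arrays were averaged per gene (1 to 5 probes per gene, 10 genes with 1), which left out 1 unnamed probe, and unnamed probes were tested singly. Symbols shared by 2 gene IDs (3 of them: aroE, carB and murC) were kept apart by ID. Disagreement among the probes of a gene was examined through the median over probes.

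Each feature was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with a coefficient for scFOS at either density against glucose, entered as 1 in Cy5 and -1 in Cy3, and a dye intercept. The residual degrees of freedom were 3 and the prior added 6.93. The 4 comparisons were scFOS at OD600 1 against glucose, scFOS at OD600 1.5 against glucose, scFOS at OD600 1.5 against scFOS at OD600 1, and the mean of the first and second. Glucose was sampled at OD600 1 alone. A feature passed with a Benjamini-Hochberg adjusted p under 0.05 over the 8797 features. All p-values are two-sided. Arrays that share an RNA sample were taken as independent. Where RNA samples vary independently, this is cautious for the first 3 comparisons and too lenient for the mean of the first and second. A difference of cultures 3 and 4 that lasts over both densities was not simulated, so how lenient the mean is stays unknown.

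Cultures 3 and 4 were each sampled at both densities, per the labels, so the culture number pairs these samples between the densities. The fit with culture as a replicate block is given where it changes a call or moves a count by over 1.5 times. Against glucose, cultures 3 and 4 are the scFOS replicates, and the block takes their difference out of the error. Its p-values can thus be too small in each comparison with glucose. As a check of the pairing, the arrays of culture 3 against culture 4 at the 2 densities were correlated. The correlation was 0.215 across features as deposited and -0.0977 after the dye intercept was removed, a step that itself pushes correlations below 0.

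The lists, 25 in number, were written by symbol before the data were examined, as were the tests, the rule for named genes and most alternative settings. Of the lists, 16 had 3 or more measured members and were tested with camera (preset correlation 0.01) in each comparison, 64 tests in all, adjusted over lists within a comparison. Camera with an estimated correlation and fry were alternatives; fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Of the 20 calls, 0 held with an estimated correlation. The 7 lists with no named member were not analysed here: both sucrose clusters, maltose and alpha-glucosidase genes, the mannose and other phosphotransferase systems, capsular polysaccharide and prophage. Catabolite control and galactose genes had under 3 members and were given as single genes.

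The rule for named genes took, per comparison, up to 12 on each side with the largest change among those passing with the same side on the arrays of the comparison, or the 10 with the smallest p where fewer than 5 passed. It added catabolite control and up to 4 members of each list past the set test. It was applied to genes with a symbol, and 2 unnamed probes per side were added, a reading settled once it was known that most probes have no name. citX, purR, atpE, galU and the genes in the closing observations were named after their values were seen.

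Alternatives changed 1 choice at a time: the dye intercept, the culture block, centring, scaling to the same median absolute deviation, quantile normalization, the probe summary, the minimum of arrays (4) or probes (2), robust variances, correlated RNA samples, thresholds, the channel reading, and each array left out. Scaling and quantile normalization give the within-scFOS arrays (SD 0.298 and 0.39) the same spread as the arrays against glucose (SD 0.472 to 0.639). This raises the replicate spread and shrinks the sugar effects, so a fall in calls was partly built in. Leaving out the RNA sample of scFOS culture 4 at OD600 1.5, using named genes as the background of the set test and leaving out arrays in the set test were chosen after seeing the data. Leaving out an array also breaks the balance of the dyes and shifts the dye intercept, so sizes with an array left out include that shift. Levels per RNA sample were solved from the loop after the dye intercept was removed, with their mean at 0.

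The fit was tested on simulated data with the array design and variances drawn from the estimated prior, 200 of 8797 features changed, 10 draws. With independent arrays, changes of 1 log2 unit were recovered in 74.2% of cases at OD600 1, 75.5% at OD600 1.5 and 96.8% for the mean of both, and changes of 2 in 99.8%, 99.7% and 100%. With variance from shared RNA samples, recovery at 1 log2 unit was 59.1%, 58.1% and 92.1%, and false calls were 2.52%, 2.00% and 6.89% of all calls. The RNA samples varied independently there, with no culture difference shared by both densities. For the difference between densities, 0 features were changed and 0 calls were made. This checks false calls alone, and the power to find such a difference was not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.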

Results

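RNA was measured from *Lactiplantibacillus plantarum* WCFS1, a lactic acid bacterium, grown in chemically defined medium with 1% of a single carbohydrate. The carbohydrate was glucose or scFOS (Actilight), a mixture of short-chain fructooligosaccharides used as a prebiotic. The study set out to find how this bacterium uses fructooligosaccharides. There were 2 cultures on glucose (cultures 1 and 2), sampled at an optical density (OD600) of 1. There were also 2 cultures on scFOS (cultures 3 and 4), each sampled at OD600 1 and 1.5. These 6 RNA samples were compared on 6 arrays with 2 dyes, arranged as a closed loop in which every sample met 2 others and carried each dye on 1 array. Each array gave a log ratio of the dyes for 9607 probes, with 1 missing value in all. The medians of the arrays lay between -0.022 and 0.0055 and the SDs between 0.298 and 0.639 log2 units. Only 1146 probes carried a gene name, for 337 genes, so that 8797 features were tested: these genes and 8460 probes without a name here. The number of arrays limits the precision.

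The sign of the ratios could not be fixed. Their values follow the dyes, but whether Cy5 was divided by Cy3 or Cy3 by Cy5 is not given in the sources used here. Changes are therefore given as sizes, with the side on which they lie. Side A means lower on scFOS (or at the higher density) if Cy5 was divided by Cy3, and higher if Cy3 was divided by Cy5. Side B is the opposite. The logarithm was read as base 2, which the sources used here do not state, so that folds and log2 units depend on that reading.

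At OD600 1, 4 of 5 genes for citrate and malate, all of them of citrate lyase, the enzyme that splits citrate, changed to side A on scFOS against glucose. The size was 1.12 ± 0.16 (SE) log2 units for citF, 1.05 ± 0.16 for citE, 0.99 ± 0.16 for citD and 0.96 ± 0.16 for citC, which encodes the ligase that activates the enzyme. These are folds of 1.95 to 2.18, and each gene lay on side A on 2 of 2 arrays, as the rule for named genes required. The other named genes that changed were purB (1.81 ± 0.28, 3.51-fold), which encodes adenylosuccinate lyase of purine synthesis, pdhA (1.71 ± 0.26, 3.26-fold), a subunit of pyruvate dehydrogenase, and ndk (1.25 ± 0.19, 2.38-fold), nucleoside diphosphate kinase. All lay on side A on 2 of 2 arrays, again a condition of that rule, with adjusted p between 0.0125 and 0.0195 in limma. With quantile normalization 1 of these 7 genes passed, citF. The largest changes were in probes without a gene name. They were probe 5440 (6.27 ± 0.29) and probe 2482 (5.995 ± 0.26) on side A, and probe 9636 (5.58 ± 0.18) and probe 7577 (5.50 ± 0.24) on side B. Sizes above 3 log2 units were reached by 18 features on side A and 11 on side B, of which 0 had a gene name.

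Among the gene lists at OD600 1, 4 of the 5 measured genes for citrate and malate changed, all 5 lay on side A, and the list as a whole lay apart from the other features. The median size was 0.99 (camera adjusted p = 1.73e-06; adjusted p = 0.598 with an estimated correlation). The fifth, citX, did not pass. The 14 purine genes all lay on side A with a median size of 0.63. Only purB passed over all features and 11 passed adjusted over the list alone (camera adjusted p = 6.58e-09; adjusted p = 0.598 with an estimated correlation). purS (0.86 ± 0.18, adjusted p = 0.0553), purE (0.83 ± 0.18, 0.0689) and purL (0.62 ± 0.17, 0.151) came next to purB by p. Whether the genes of this list, or of the citrate and amino acid lists, lie together on the chromosome was not examined. In each comparison they need not be separate observations. Of 36 amino acid biosynthesis genes 27 lay on side B, 0 passed over all features and 4 adjusted over the list alone (camera adjusted p = 7.37e-05; adjusted p = 0.598 with an estimated correlation). The smallest p in that list belonged to aroE (gene ID 1062996; 0.76 ± 0.16, adjusted p = 0.0642) of aromatic amino acid synthesis and to hisI (0.85 ± 0.20), hisH (0.61 ± 0.17) and hisD (0.66 ± 0.18) of histidine synthesis. Of 13 aminoacyl-tRNA synthetases 12 lay on side B, and 0 passed singly or adjusted over the list alone (camera adjusted p = 0.000476; adjusted p = 0.631 with an estimated correlation). The smallest p belonged to glyS (0.41 ± 0.17), alaS (0.39 ± 0.18), thrS (0.38 ± 0.18) and hisS (0.36 ± 0.21). With fry the citrate list passed (adjusted p = 0.0146), while purines and amino acid biosynthesis (0.186 each) and the synthetases (0.215) did not. Ribosomal proteins (camera adjusted p = 0.102, 0 of 51 past), pyrimidine (0.65, 0 of 3) and fatty acid biosynthesis (0.115, 0 of 3, and 2 adjusted over the list alone) did not pass at OD600 1. The list calls for amino acid biosynthesis and for the synthetases ended without the array of glucose culture 2 and scFOS culture 4 (adjusted p = 0.129) and that of glucose culture 1 and scFOS culture 3 (0.0519), respectively. Without these the size of alaS was 0.53 and 0.25. With culture as a replicate block purS (adjusted p = 0.0159), purE (0.0165), aroE (0.0269) and hisI (0.0149) passed. The counts were then 3 of 14 purine and 2 of 36 amino acid biosynthesis genes, 2 of 51 ribosomal genes on side A and 1 of 3 fatty acid genes. Against glucose the block takes the difference between the scFOS replicates out of the error, so these p-values can be too small. purE also passed without either OD600 1.5 array of scFOS against glucose (0.0448 each). Without the sample of scFOS culture 4 at OD600 1.5, an alternative chosen after seeing the data, purS (0.0411), purE (0.0391) and hisI (0.0372) passed, as did the fatty acid and pyrimidine lists on side B (0.0221 each; with all arrays, adjusted p = 0.631 and adjusted p = 0.836 with an estimated correlation). The fatty acid list passed on side B without the array of glucose culture 1 and scFOS culture 3 (0.0388) or either OD600 1.5 array of scFOS against glucose (0.0493 each). Pyruvate dissipation genes, not past here (camera adjusted p = 0.0821), passed on side A with the block (0.0431), with no dye intercept (0.0377), without the array of glucose culture 2 and scFOS culture 4 (0.0349), without the within-scFOS array at OD600 1.5 (0.0428) and without that sample (0.0248). With all arrays this list had adjusted p = 0.598 with an estimated correlation. Chaperones passed on side B without the array of glucose culture 1 and scFOS culture 3 (0.00372; with all arrays, adjusted p = 0.836 with an estimated correlation).

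In all, 113 features passed an adjusted p of 0.05 at OD600 1 (limma, Benjamini-Hochberg), 78 on side A and 35 on side B, and the 7 genes among them all lay on side A. An unadjusted p under 0.05 was reached by 1040 features, where chance alone gives about 440. With culture as a replicate block the count was 295, with 12 genes on side A and 3 on side B, with quantile normalization 32 (16 on side A and 16 on side B, with 1 and 0 genes), and with arrays scaled to the same spread 54. It was 212 without the sample of scFOS culture 4 at OD600 1.5, with 10 genes on side A and 3 on side B. The count fell to 27 without the array of glucose culture 2 and scFOS culture 4, 42 without that of glucose culture 1 and scFOS culture 3 and 35 without the within-scFOS array at OD600 1. The p-values rest on 2 cultures per sugar. Without the first or the second of these arrays 0 genes passed, and 2 did without the third.

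In scFOS at OD600 1.5 against glucose at OD600 1, density differed along with the sugar. On side B 21 of 51 ribosomal protein genes and 2 of 3 fatty acid genes passed, and on side A 4 of 14 purine genes, 4 of 5 citrate genes and 1 ribosomal gene. The camera calls for these lists were lost, with adjusted p = 0.426 with an estimated correlation for ribosomal proteins and adjusted p = 0.492 with an estimated correlation for the others. With fry the citrate list passed (adjusted p = 0.0185), while ribosomal proteins (0.0519), fatty acids (0.0899) and purines (0.113) did not. Among named genes that passed, the largest sizes were those of fabF (2.11 ± 0.29, 4.3-fold, adjusted p = 0.00244) and fabI (1.83 ± 0.25, 3.56-fold, 0.00234). They encode enzymes of fatty acid chain elongation. Both lay on side B on 2 of 2 arrays, which the rule for named genes required. Larger but not past were pyrE (2.61 ± 0.76), carB (gene ID 1062982; 2.60 ± 0.77) and pyrF (2.26 ± 0.67) on side A. Among those past on side A the largest were asp1 (1.76 ± 0.18, 3.38-fold, adjusted p = 0.000557), purH (1.26 ± 0.29, 0.026), purM (1.16 ± 0.25, 0.0189), the ribosomal protein gene rpsU (1.16 ± 0.19, 0.00584) and tpx (1.09 ± 0.16, 0.0031), which encodes thiol peroxidase. Some sizes moved with 1 array left out. Without that of glucose culture 2 and scFOS culture 3, fabF was 1.25, fabI 1.13, purH 0.76 and rpsU 0.73. Without that of glucose culture 1 and scFOS culture 4 they were 2.96, 2.54, 1.76 and 1.59. The single arrays with scFOS culture 4 and culture 3 gave 1.54 and 2.67 for fabF, and 1.36 and 2.3 for fabI. These ranges are narrower, as leaving out an array also shifts the dye intercept.

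Ribosomal protein genes formed the largest group at OD600 1.5. Of 51 measured, 21 changed to side B, 1 to side A (rpsU) and 29 did not pass. Adjusted over the list alone, 28 passed on side B and 2 on side A. Their median size was 0.52 on side B (camera adjusted p = 1.73e-10; adjusted p = 0.426 with an estimated correlation). Examples are rpsQ (1.05 ± 0.18), rplO (1.04 ± 0.17), rplW (1.03 ± 0.20) and rpsC (1.02 ± 0.16), followed by rpmC, rplF, rplC and rplP with 0.94 to 0.97. trmD, a tRNA methyltransferase gene, changed with them (1.06 ± 0.20). Whether the ribosomal genes that passed, here or over both densities, lie together on the chromosome was not examined. They need not be separate observations, nor stand for all ribosomal protein genes. Without the sample of scFOS culture 4 at OD600 1.5, 4 ribosomal genes passed on side B and 2 on side A, and with culture as a replicate block 25 and 3.

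Of the 14 purine genes at OD600 1.5, 4 changed, all to side A, and adjusted over the list alone 10 passed on side A and 1 on side B (camera adjusted p = 0.000295; adjusted p = 0.492 with an estimated correlation). Besides purH and purM these were guaB (1.00 ± 0.22), IMP dehydrogenase, and purN (0.93 ± 0.20). upp, which encodes uracil phosphoribosyltransferase, lay on the same side (0.94 ± 0.19, adjusted p = 0.016). purR, a regulator of purine genes rather than an enzyme, was the member on side B (0.66, adjusted p = 0.0758 over all features). The citrate lyase genes citE (0.88 ± 0.16), citF (0.87 ± 0.16), citC (0.80 ± 0.16) and citD (0.62 ± 0.16) changed to side A, 4 of 5 in the list both over all features and adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.492 with an estimated correlation). Without the sample of scFOS culture 4 at OD600 1.5, 4 purine genes and 0 citrate genes passed. The block on culture gave 8 purine genes on side A and 1 on side B. Without the array of glucose culture 2 and scFOS culture 3 or that of glucose culture 1 and scFOS culture 4, the sizes were 1.47 and 0.52 for guaB, 0.50 and 1.36 for purN, 0.54 and 1.34 for upp, and 0.76 and 1.76 for purH.

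Amino acid biosynthesis genes changed to side B in 6 of 36 cases, 9 adjusted over the list alone (camera adjusted p = 0.000197; adjusted p = 0.492 with an estimated correlation). Those with the smallest p were aroA (1.21 ± 0.20, 2.32-fold), aroE (gene ID 1062996; 0.81 ± 0.16), aroB (0.80 ± 0.18) and hisH (0.72 ± 0.17). All 13 aminoacyl-tRNA synthetases lay on side B, and argS (0.67 ± 0.15) and glyS (0.64 ± 0.17) changed. Adjusted over the list alone 4 passed (camera adjusted p = 0.000286; adjusted p = 0.492 with an estimated correlation), while thrS (0.67 ± 0.18) and ileS (0.49 ± 0.16) did not pass over all features. thrS passed with culture as a replicate block (adjusted p = 0.0204). Without the array of glucose culture 2 and scFOS culture 3 the sizes were 0.39 for glyS, 0.30 for thrS and 0.29 for ileS, and without that of glucose culture 1 and scFOS culture 4 they were 0.88, 1.03 and 0.69. In fatty acid biosynthesis fabF and fabI changed, 2 of 3 by either adjustment, while fabG gave 0.14 ± 0.17 on side A (camera adjusted p = 0.0191; adjusted p = 0.492 with an estimated correlation). The 3 pyrimidine genes lay on side A, with 0 of 3 past over all features, 2 of 3 with culture as a replicate block and 2 adjusted over the list alone (camera adjusted p = 0.0476; adjusted p = 0.492 with an estimated correlation). Here pyrE gave 2.61 ± 0.76 (adjusted p = 0.0616), pyrF 2.26 ± 0.67 (0.0655) and pyrH 0.38 ± 0.17. These were 0.62, 0.49 and 0.10 without the array of glucose culture 1 and scFOS culture 4 (fabG 0.025), and without that of glucose culture 2 and scFOS culture 3 they were 4.60, 4.04 and 0.66 (fabG 0.25). With the block the adjusted p was 0.000112 for pyrE and 0.000235 for pyrF, and without the within-scFOS array at OD600 1.5 it was 0.00116 and 0.00169. The block takes the difference between cultures 3 and 4, the scFOS replicates, out of the error, so its p-values can be too small here. Without the sample of scFOS culture 4 at OD600 1.5 pyrE passed with 1.29 (0.0492). For pyrE the single arrays gave 3.94 with scFOS culture 4 and 1.28 with scFOS culture 3.

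In all, 748 features passed at OD600 1.5, 437 on side A and 311 on side B, and 51 genes were among them, 12 on side A and 39 on side B. With either rescaling 1 gene passed on side A and 2 on side B, too few to judge this split. Without the array of glucose culture 2 and scFOS culture 3 the genes on side A and B numbered 3 and 0. They numbered 6 and 7 without that of glucose culture 1 and scFOS culture 4. The excess on side B was thus small or absent without either array. An unadjusted p under 0.05 was reached by 2348 features. The largest changes were again in unnamed probes, 9636 (5.81 ± 0.18) and 7577 (5.67 ± 0.24) on side B and 6704 (5.12 ± 0.27) and 2482 (4.94 ± 0.26) on side A. The count was 1228 with culture as a replicate block, with 24 genes on side A and 51 on side B, 267 with no dye intercept, 81 with arrays scaled to the same spread, and 64 with quantile normalization, which also turned the split to 26 on side A and 38 on side B. With either of the latter 0 ribosomal genes passed. Both settings give the within-scFOS arrays the spread of the arrays against glucose, so a fall in calls was partly built in. The count fell to 148 without the array of glucose culture 2 and scFOS culture 3, where 0 ribosomal, fatty acid and citrate genes passed. It fell to 280 without that of glucose culture 1 and scFOS culture 4, where 4 ribosomal genes on side B and 0 citrate genes passed, and to 315 without the sample of scFOS culture 4 at OD600 1.5, with 9 genes on side A and 8 on side B. Without the first of these the list calls for amino acid biosynthesis, purines and the synthetases (adjusted p = 0.13 each) and fatty acids (0.115) ended, and without the second the pyrimidine call (0.792). Without the within-scFOS array at OD600 1 the calls for fatty acids (0.0905) and pyrimidines (0.125) ended, and without the sample of scFOS culture 4 at OD600 1.5 that for pyrimidines (0.0516).

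**Figure D1:**
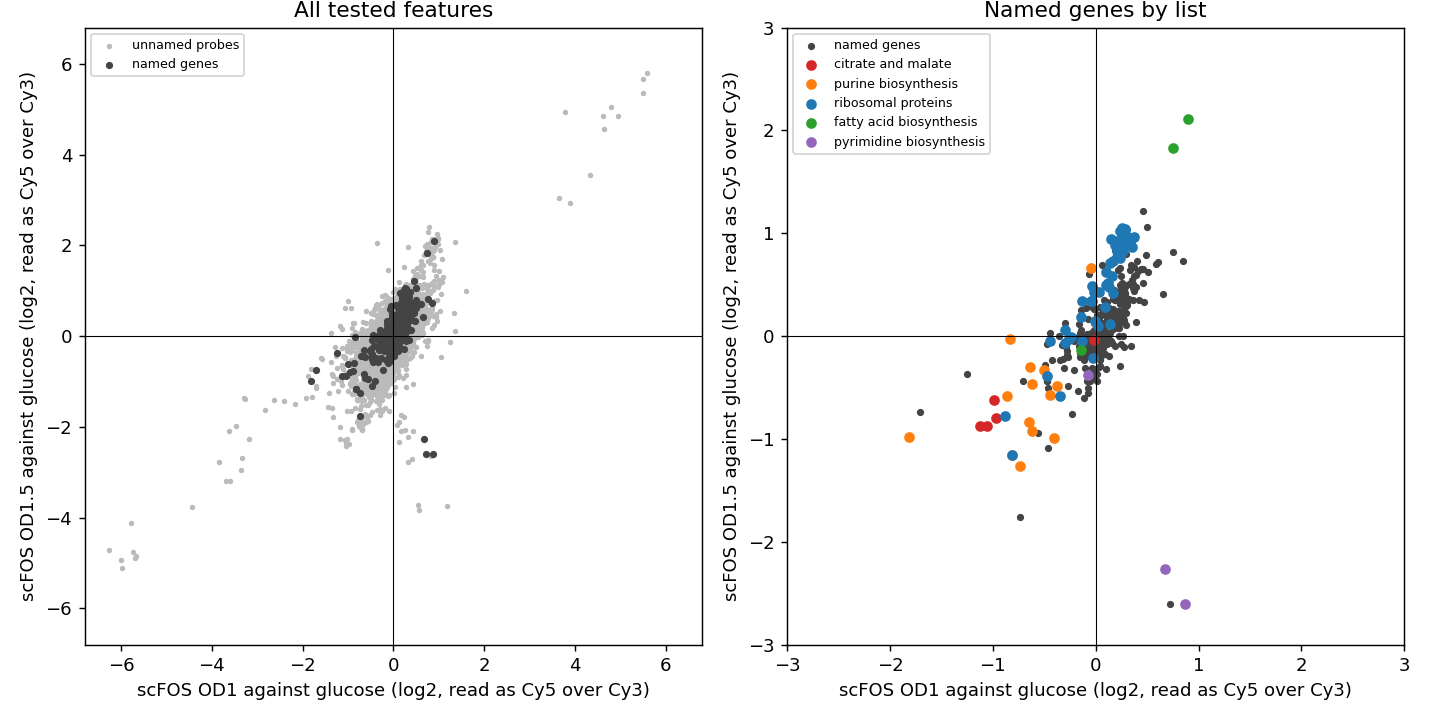
Size and side of the scFOS effect at OD600 1 (horizontal axis) and at OD600 1.5 (vertical axis), each against glucose, in log2 units read as Cy5 over Cy3, so that values below 0 lie on side A and values above 0 on side B. Grey points are unnamed probes, dark points the 337 named genes, and in the right panel coloured points the members of 5 gene lists; all sizes above 3 on either axis belong to unnamed probes, the ribosomal genes spread upwards, and pyrE and pyrF lie at the lower right with 2.61 and 2.26 on the vertical axis. Both axes use the same glucose samples.

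The comparison of scFOS at OD600 1.5 with scFOS at OD600 1 compared levels at the 2 densities within the scFOS cultures. Glucose was not sampled at OD600 1.5, so whether the response to scFOS depends on density was not tested. Ribosomal protein genes lay on side B as a group: 47 of 51 lay on that side, with a median size of 0.48 (camera adjusted p = 1.39e-12; adjusted p = 0.332 with an estimated correlation), while 0 passed singly, over all features or adjusted over the list alone. The 3 pyrimidine genes lay on side A (camera adjusted p = 0.00737; adjusted p = 0.606 with an estimated correlation), with pyrE at 3.48 ± 1.07, pyrF at 2.93 ± 0.94 and pyrH at 0.31 ± 0.24. These were 1.49, 1.16 and 0.028 without the array of glucose culture 1 and scFOS culture 4, and without that of glucose culture 2 and scFOS culture 3 they were 5.47, 4.71 and 0.59. Over all features 0 passed, adjusted over the list alone 2, and with culture as a replicate block pyrE (adjusted p = 0.00623) and pyrF (0.00912). The 3 fatty acid genes lay on side B (camera adjusted p = 0.0329; adjusted p = 0.606 with an estimated correlation), with fabF at 1.21 ± 0.41 and fabI at 1.08 ± 0.35, and fabG at 0.0053 ± 0.23, whose side changed under some alternatives. Without the array of glucose culture 2 and scFOS culture 3, fabF was 0.36 and fabI 0.38, and without that of glucose culture 1 and scFOS culture 4 they were 2.06 and 1.78. Again 0 passed over all features and 2 adjusted over the list alone.

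No feature (0 of 8797) passed the difference between densities in limma, where the smallest adjusted p was 0.153 and 588 features had an unadjusted p under 0.05 against about 440 by chance. The 10 named genes with the smallest p, none past the threshold, were asp1 (1.02 ± 0.26 on side A, adjusted p = 0.541), rpsC (0.78 ± 0.23), ndk (0.88 ± 0.27), rpsQ (0.79 ± 0.25), purE (0.81 ± 0.26), fabI and rplO (0.76 ± 0.25) on side B, and pyrE, pyrF and carB (gene ID 1062982; 3.33 ± 1.08) on side A, each after asp1 with an adjusted p of 0.701. carB encodes the large subunit of carbamoyl phosphate synthase, whose product feeds pyrimidine and arginine synthesis. rpsN, a further ribosomal gene, gave 0.71 ± 0.24 on side B. Among genes with an unadjusted p under 0.05, 24 lay on side B and 5 on side A. With culture as a replicate block, which uses that cultures 3 and 4 were each sampled at both densities, 35 features passed (26 on side A and 9 on side B), with 3 genes among them: pyrE (adjusted p = 0.00623), pyrF (0.00912) and carB (0.00912). With arrays that share an RNA sample taken as correlated, 3 passed. Without the within-scFOS array at OD600 1.5, 20 passed, among them pyrE (0.0372), pyrF (0.0388) and carB (0.047). Without the array of glucose culture 1 and scFOS culture 4, carB gave 1.13, and without that of glucose culture 2 and scFOS culture 3 it gave 5.53. These ranges were 0.47 to 1.15 for purE and 0.49 to 1.03 for rplO, and with either OD600 1 array of scFOS against glucose left out 0.55 and 1.21 for ndk and 0.67 and 1.38 for asp1. Without the array of glucose culture 2 and scFOS culture 3, 2 features passed, and without the sample of scFOS culture 4 at OD600 1.5, 4. The pyrimidine call ended without the within-scFOS array at OD600 1 (adjusted p = 0.0731) or that of glucose culture 1 and scFOS culture 4 (0.369). The fatty acid call ended without the within-scFOS array at OD600 1 (0.139), without that of glucose culture 1 and scFOS culture 3 (0.131) or without that of glucose culture 2 and scFOS culture 3 (0.529). Without the array of glucose culture 1 and scFOS culture 4, amino acid biosynthesis (0.00285), the synthetases (0.00399) and ATP synthase (0.00399) passed on side B, as they did without the sample of scFOS culture 4 at OD600 1.5 (0.00805, 0.0296 and 0.0259). With all arrays each of these lists had adjusted p = 0.806 with an estimated correlation. Amino acid biosynthesis also passed without the array of glucose culture 2 and scFOS culture 4 (0.038), and chaperones on side A without that of glucose culture 1 and scFOS culture 3 (0.00775; with all arrays, adjusted p = 0.904 with an estimated correlation).

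**Figure D2:**
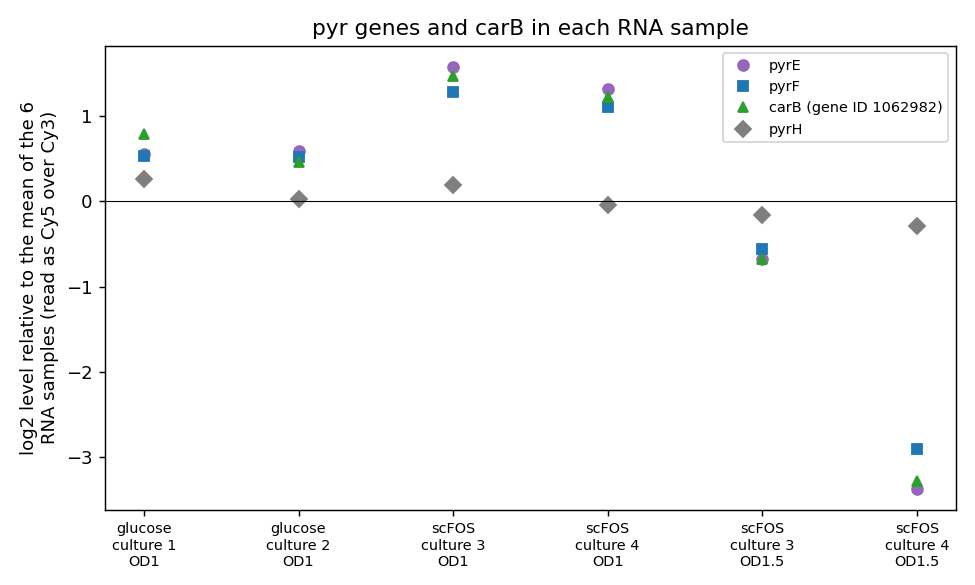
Level of pyrE, pyrF, carB (gene ID 1062982) and pyrH in each of the 6 RNA samples, relative to their mean, in log2 units solved from the loop and read as Cy5 over Cy3 (turned upside down if Cy3 was divided by Cy5). Each point is 1 RNA sample with no error of its own; for pyrE the scFOS samples at OD600 1 lie at 1.58 and 1.32, the glucose samples at 0.56 and 0.60, and the scFOS samples at OD600 1.5 at -0.68 (culture 3) and -3.38 (culture 4).

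The mean of scFOS at both densities was set against glucose at OD600 1, so density differed in part of this comparison. On side A 9 of 14 purine genes and 4 of 5 citrate genes passed. On side B 19 of 51 ribosomal protein genes passed, with 2 on side A, and 0 of 51 had passed at OD600 1. Also on side B were 8 of 36 amino acid biosynthesis genes, 3 of 13 aminoacyl-tRNA synthetases and 2 of 3 fatty acid genes. The camera calls for these 6 lists were lost, each with adjusted p = 0.435 with an estimated correlation. With fry, which does not compare a list with other genes, all 6 passed. The adjusted p was 0.00743 for citrate genes and 0.0477 for each of the others. Among named genes that passed, the largest on side A were purB (1.40 ± 0.20, 2.63-fold), asp1 (1.24 ± 0.13), pdhA (1.22 ± 0.19) and citF (1.00 ± 0.12). On side B they were fabF (1.50 ± 0.20, 2.83-fold), fabI (1.29 ± 0.17), aroA (0.84 ± 0.14) and hisI (0.79 ± 0.14). Each of these lay on its side on 4 of 4 arrays that set scFOS against glucose, which the rule for named genes required. These arrays share the same glucose samples. The adjusted p in limma lay between 0.00045 and 0.00608.

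Of the 14 purine genes 9 changed to side A, 13 adjusted over the list alone (camera adjusted p = 1.47e-06; adjusted p = 0.435 with an estimated correlation), with purH (1.00 ± 0.21), purM (0.98 ± 0.18), purN (0.77 ± 0.14) and purS (0.73 ± 0.13) next to purB. Of the 5 citrate genes 4 changed to side A by either adjustment, with citE at 0.96 ± 0.11, citC at 0.88 ± 0.11 and citD at 0.81 ± 0.11 (camera adjusted p = 0.000138; adjusted p = 0.435 with an estimated correlation). Of the 51 ribosomal protein genes 19 changed to side B and 2 to side A, 24 and 2 adjusted over the list alone (camera adjusted p = 5.52e-07; adjusted p = 0.435 with an estimated correlation). rpmC (0.67 ± 0.12), rplO (0.66 ± 0.12), rplW (0.66 ± 0.14), rpsQ (0.66 ± 0.13) and rpsC (0.63 ± 0.12) led on side B, and rpsU (0.99 ± 0.13) lay on side A. Of 36 amino acid biosynthesis genes 8 changed to side B, 14 adjusted over the list alone (camera adjusted p = 1.73e-05; adjusted p = 0.435 with an estimated correlation), among them aroE (gene ID 1062996; 0.79 ± 0.12) and hisH (0.66 ± 0.12). Of 13 aminoacyl-tRNA synthetases glyS (0.52 ± 0.12), thrS (0.52 ± 0.13) and argS (0.45 ± 0.11) changed to side B, 7 adjusted over the list alone (camera adjusted p = 4.49e-05; adjusted p = 0.435 with an estimated correlation). alaS (0.43 ± 0.13) did not pass, but did with culture as a replicate block (adjusted p = 0.0231), where 5 synthetases passed. The p-values of that fit can be too small against glucose. thrS was 0.34 without the array of glucose culture 2 and scFOS culture 3 and 0.71 without that of glucose culture 1 and scFOS culture 4. In fatty acid biosynthesis 2 of 3 changed to side B by either adjustment, and fabG gave 0.14 ± 0.12 on side A (camera adjusted p = 0.0382; adjusted p = 0.435 with an estimated correlation). Further genes that changed were ndk (0.81 ± 0.13) and tpx (0.78 ± 0.11) on side A, and trmD (0.78 ± 0.14) and mutS (0.64 ± 0.11), a DNA mismatch repair gene, on side B. The fatty acid call ended without the within-scFOS array at OD600 1 (adjusted p = 0.151). Against named genes as background, chosen after seeing the data, it ended here (0.285), at OD600 1.5 (0.244) and between the densities (0.269), as did that for amino acid biosynthesis at OD600 1.5 (0.0593).

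Pyrimidine biosynthesis did not pass over both densities (camera adjusted p = 0.338, 0 of 3 past). With culture as a replicate block 2 of 3 passed on side A, and without the array of glucose culture 2 and scFOS culture 3 the list passed on that side (adjusted p = 0.0245; with all arrays, adjusted p = 0.839 with an estimated correlation). In the main fit the other lists did not pass camera in any of the 4 comparisons, with camera adjusted p between 0.338 and 0.847 over both densities. Pyruvate dissipation at OD600 1 passed camera with the block or with no dye intercept, as given above. With fry, redox genes passed at OD600 1.5 (adjusted p = 0.0185) and over both densities (0.0243). Pyruvate dissipation and peptidases also passed fry over both densities (0.0477 each), all on side A. None of these lists passed with an estimated correlation. Over both densities, 0 of 5 glycolysis genes, 0 of 6 ATP synthase genes, 0 of 5 pentose and other sugar genes, 0 of 12 chaperone and protease genes, 0 of 3 plantaricin genes, 0 of 3 D-alanylation genes and 0 of 3 peptidase genes changed. The counts adjusted over the list alone were also 0. With the block 1 ATP synthase gene passed, on side B, and at OD600 1.5 also 1 of 3 genes for pyruvate dissipation, on side A. Redox genes passed against named genes as background at OD600 1.5 (0.0409) and between densities (0.0228), both on side A. Against all features the list had adjusted p = 0.492 and adjusted p = 0.656 with an estimated correlation, respectively. Of the 3 genes for pyruvate dissipation pdhA changed, and of the 4 for redox and oxygen stress tpx, 1 each also adjusted over the list alone. At OD600 1.5, 1 of 6 ATP synthase genes, atpE, changed to side B (0.69 ± 0.16, adjusted p = 0.0307). Of lists too small for the set test, galU changed (0.45 ± 0.12 on side A, adjusted p = 0.0395), while the catabolite control genes ccpA (0.35 ± 0.15 on side B, adjusted p = 0.154) and hprK (0.065 ± 0.11 on side A, 0.713) did not pass. At OD600 1 ccpA gave 0.29 ± 0.22 and hprK 0.16 ± 0.15, at OD600 1.5 they gave 0.41 ± 0.22 and 0.026 ± 0.15, and their differences between densities were 0.12 ± 0.30 and 0.18 ± 0.22. ccpA was 0.014 at OD600 1.5 and 0.15 over both densities, and hprK 0.0085 at OD600 1.5, without the array of glucose culture 1 and scFOS culture 4. Without that of glucose culture 2 and scFOS culture 3 these were 0.81, 0.55 and 0.043. Between densities ccpA then turned to side A with -0.28 and lay on side B with 0.52, respectively. The median, mean and test lay on different sides for D-alanylation and redox at OD600 1, for pentose genes, ATP synthase and chaperones at OD600 1.5, and for peptidases, plantaricin and chaperones between densities, so these have no side.

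In all, 1085 features passed over both densities, 587 on side A and 498 on side B, of which 23 and 47 were genes, and 2648 had an unadjusted p under 0.05. The excess of genes on side B turned with arrays scaled to the same spread (12 on side A and 6 on side B) and with quantile normalization (9 and 7). In both settings a fall in calls was partly built in. Of unnamed probes, 9636 (5.70 ± 0.13) on side B and 6704 (5.55 ± 0.19) on side A changed most. The count was 674 with arrays that share an RNA sample taken as correlated, 429 with no dye intercept, 370 with arrays scaled to the same spread and 284 with quantile normalization (130 on side A and 154 on side B), where 1 purine gene and 0 ribosomal genes on side B passed. The count fell to 270 without the array of glucose culture 2 and scFOS culture 4, 386 without that of glucose culture 1 and scFOS culture 3 and 410 without that of glucose culture 2 and scFOS culture 3. The genes past were then 10 on side A and 2 on side B, 14 and 9, and 10 and 5. Ribosomal genes on side B numbered 0, 1 and 0, and 4 citrate genes passed each time.

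**Figure D3:**
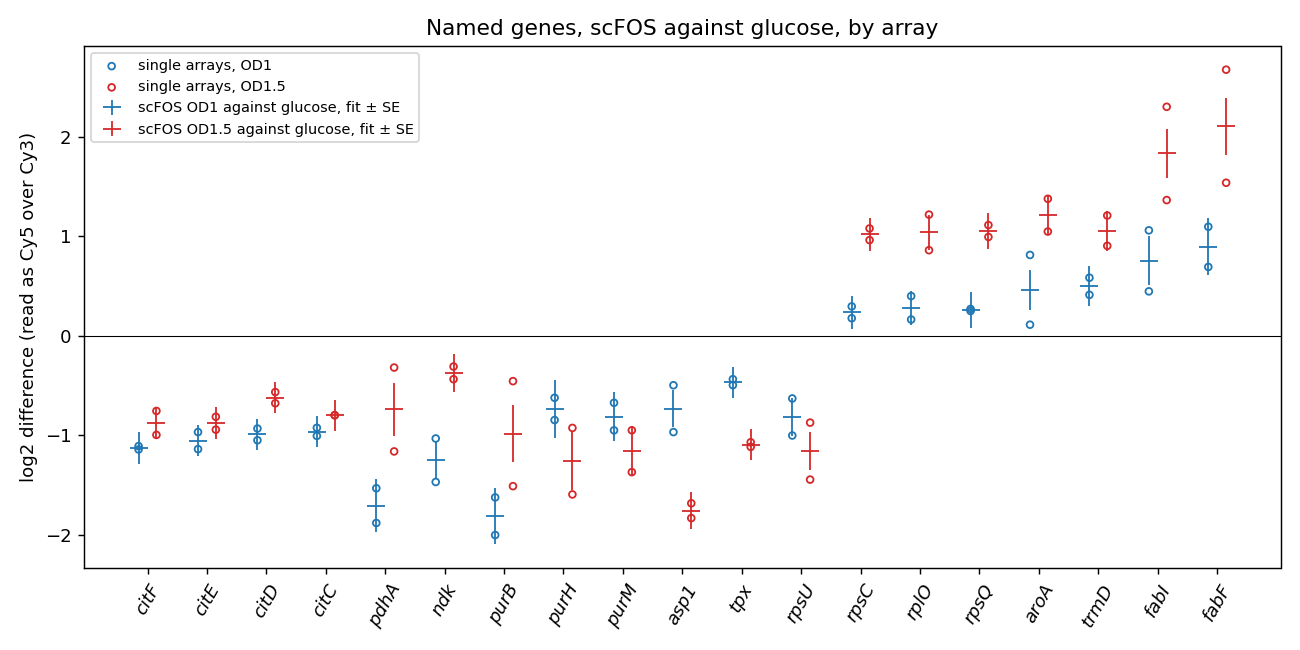
Difference between scFOS and glucose for 19 named genes in log2 units read as Cy5 over Cy3 (below 0 is side A, above 0 side B), at OD600 1 in blue and OD600 1.5 in red. Open circles are the 2 arrays of each comparison after removal of the dye intercept, and bars the fitted value ± SE; the citrate lyase genes lie between 0.62 and 1.12 on side A at either density, and fabF reaches 2.11 on side B at OD600 1.5.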

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

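All tests of explanations in this part were chosen after the results were seen. Within the scFOS cultures, 3 gene lists differed between OD600 1 and OD600 1.5 by the set test, which cannot say whether the response to scFOS depends on density, as glucose was not sampled at OD600 1.5: ribosomal proteins (adjusted p = 1.39e-12), pyrimidine biosynthesis (0.00737) and fatty acid biosynthesis (0.0329). None of the 3 passed with an estimated correlation (adjusted p = 0.332, 0.606 and 0.606) or with fry (adjusted p = 0.453, 0.457 and 0.457). Only genes picked by the rule for named genes were examined for a turn of side between the densities. Among these, pyrE, pyrF, carB (gene ID 1062982) and hprK lay on one side on both arrays at OD600 1. They lay on the other on both arrays at OD600 1.5. Their differences were 3.48, 2.93, 3.33 and 0.18 log2 units, and none passed the test of the difference (adjusted p = 0.701, 0.701, 0.701 and 0.909). With culture as a replicate block pyrE (0.00623), pyrF (0.00912) and carB (0.00912) passed it. Leaving out 1 array gave 1.49 to 5.47 for pyrE, 1.16 to 4.71 for pyrF and 1.13 to 5.53 for carB, lowest without the array of glucose culture 1 and scFOS culture 4 and highest without that of glucose culture 2 and scFOS culture 3.

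The genes carB, pyrE and pyrF stood apart in the RNA sample of scFOS culture 4 at OD600 1.5, which differed from culture 3 at that density by 2.69 in pyrE, 2.35 in pyrF and 2.61 in carB on the array that set them together, after removal of the dye intercept. An artefact of 1 array would leave the sum round the loop off by about that size, but the median sum over the 3 genes was -0.322. This argues against such an artefact only weakly. The sum also holds the dye effect of each gene, which could mask an array error, and its SD over all features is 1.42. A glucose sample under this label is argued against by the 24 features with changes above 3 in the mean of both densities. There the sample differed from scFOS culture 3 by a median of 0.428 and from glucose culture 1 by 4.32, a ratio of 0.0991. That mean includes this sample, so the choice favoured features in which it differs from glucose. A change with density in both cultures stays open. Over the pyrimidine list (pyrE, pyrF and pyrH) the median change from OD600 1 to OD600 1.5 was -1.84 in culture 3 and -4.02 in culture 4, read as Cy5 over Cy3, but pyrE and pyrF had been picked for lying on opposite sides at the 2 densities on the arrays of culture 3 too, so this decides nothing. pyrH, the 1 member not so picked, did not stand apart: it changed by -0.358 in culture 3 and -0.255 in culture 4.

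Whether a single culture carried the shift of the ribosomal protein genes with density stays open. Its median was 0.367 in culture 3 and 0.502 in culture 4, and 44 of 51 genes followed it in each. But 0 arrays compare the densities within a culture. Both shifts are solved from the same 6 arrays, so that independent array errors alone correlate them by 0.333. The median difference over the list was 0.0302 and 0.198 between cultures 3 and 4 at OD600 1 and 1.5, and 0.207 between the glucose cultures. A shift common to all genes cannot be weighed, because array medians near 0 leave no room for it in the values. The median of the other 286 named genes was 0.0348, against 0.475 in the ribosomal genes. The 95% bootstrap interval of the former was 0.0053 to 0.072 (2000 draws, genes taken as independent). The ribosomal genes thus moved relative to the other named genes, which says nothing of a shift that all share. A dependence of the ratios on intensity, which strongly expressed genes would share, was not tested, and density cannot be parted from the time of growth in this design. With any 1 array left out the set call for this list between densities did not end, which argues against a single array as its source. The 4 members with the smallest p then ranged from 0.69 to 0.87 (rpsC), 0.70 to 0.88 (rpsQ), 0.49 to 1.03 (rplO) and 0.60 to 0.82 (rpsN). That call was itself lost with an estimated correlation (adjusted p = 0.332) and with fry (adjusted p = 0.453). The shift may be biological, come from intensity or rest on 1 culture.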

How the results depend on the processing

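The alternative without the RNA sample of scFOS culture 4 at OD600 1.5 and the named-gene background were chosen after seeing the data, as were the set tests with arrays left out; the others were chosen before. Counts are given in the order OD600 1, OD600 1.5, difference between densities, mean of both, where the reported counts are 113, 748, 0 and 1085. With no dye intercept the first, second and last were 31, 267 and 429; with arrays scaled to the same spread 54, 81 and 370; with quantile normalization 32, 64 and 284, all among the reported calls. With culture as a replicate block the first 3 were 295, 1228 and 35, and the last 1548. The block also changed 11 calls of named features and 1 list call (pyruvate dissipation at OD600 1), all gained, and ended 0. Against glucose it takes the difference between the scFOS replicates out of the error, so the gains there can be too lenient. With at least 2 probes, which leaves 327 features, they were 8, 69 and 96 for the first, second and last; with a fold of at least 2 as well, 69, 298 and 168; at an adjusted p under 0.10, 178, 1401 and 1818. With RNA samples correlated the difference gave 3 and the mean 674. Without scFOS culture 4 at OD600 1.5 the first 3 were 212, 315 and 4. Leaving out each array gave 27 to 130, 148 to 809, 0 to 20 and 270 to 1245, and 15 to 22 list calls. Of the 20 list calls 0 passed with an estimated correlation. fry gave 12 list calls, 4 of them for lists that had not passed. Centring, the median over probes, single probes, at least 4 arrays and robust variances kept every count within 1.5 times. No scaling moved the median of all features by over 0.1. Scaling and quantile normalization raise the spread of the within-scFOS arrays to that of the arrays against glucose, so part of their fall in calls was built in. Otherwise the cause of these changes was not tested, apart from the fewer features, fewer arrays or other threshold that the setting itself brings.

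Of 2377 values of named features under alternatives, 1923 kept their side and their side of the threshold, 372 lost the threshold, 45 gained it and 37 turned to the other side. The reading channel 2 over channel 1 turns the within-scFOS array at OD600 1.5. It also turns 1 of the 2 OD600 1.5 arrays of scFOS against glucose, and the correlation of these 2 argues against it. This reading gave 0 calls in each comparison and 30 of the turned values. In this paragraph a value below 0 lies on the side opposite to the reported one, whichever that is. At OD600 1.5 these were rpsQ -0.068, rpmC -0.13, rplF -0.0097, asp1 -0.0079, purM -0.050, tpx -0.19, guaB -0.51, citE -0.16, citC -0.092, probe 6704 -0.39, probe 2482 -0.26, ccpA -0.23, hprK -0.00028, argS -0.059, pyrE -1.44, pyrF -1.21, pyrH -0.34 and fabG -0.22. Between densities they were asp1 -0.74, rpsC -0.13, pyrE -0.57, rpsQ -0.33, pyrF -0.54, fabI -0.086, rplO -0.067, carB -0.80, ccpA -0.52, pyrH -0.41 and fabF -0.10, and for the mean fabG -0.040. The others were genes near 0: with the median over probes hprK -0.021 at OD600 1.5 and fabG -0.028 between densities; between densities, with arrays left out, fabG from -0.11 to 0.12 (-0.047 without glucose culture 2 and scFOS culture 4) and ccpA from -0.28 to 0.52, and ccpA -0.14 without the sample of scFOS culture 4 at OD600 1.5, where fabG at OD600 1.5 was -0.0044. The cause was not tested for these. Signal over background was not analysed, so that no limit from it can be given.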

Other observations

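The genes and tests in this part were chosen after their values were seen. Over both densities, further single genes passed on side B. Among them were parC (0.64 ± 0.12, adjusted p = 0.00739) and parE (0.52 ± 0.12, 0.0199), which encode topoisomerase IV, recG (0.49 ± 0.11, 0.0216), a DNA helicase, and ligA (0.41 ± 0.11, 0.0402), DNA ligase, and also typA (0.56 ± 0.12), nusA (0.57 ± 0.12), gatB (0.45 ± 0.11), pth (0.48 ± 0.13), tgt (0.43 ± 0.12), rimM (0.41 ± 0.11) and secY (0.52 ± 0.11), the channel of protein export. On side A, the second ribosomal protein gene to pass besides rpsU was rpsA (0.46 ± 0.11, adjusted p = 0.0264), and narH (0.57 ± 0.14, 0.0309), a subunit of nitrate reductase, and glyA (0.45 ± 0.11, 0.0292), serine hydroxymethyltransferase, passed as well. These genes form no list fixed beforehand, and no enrichment was tested.

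The direction of the deposited ratios was weighed by the ribosomal protein genes. If growth had slowed by OD600 1.5, these genes would be expected to be lower there, which is what side B means if Cy3 was divided by Cy5. They lay on side B, but with an estimated correlation the adjusted p was 0.332, and growth rate is not given in the sources used here. Whether Cy3 was divided by Cy5 or the reverse cannot be told apart by this test.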
